A study of Homo sapiens with 12 samples.

How the data were processed

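Total RNA of 12 human fibroblast samples was measured on Affymetrix arrays, in 4 groups of 3: CAFs with a control hairpin, CAFs with a hairpin construct against NNMT, WI-38 with a control construct and WI-38 with an NNMT construct. Per the labels' protocols, cells were stably infected with the constructs and grown for 21 days in methionine-free medium with 10% dialyzed serum and 10 µM methionine. Per the same protocols, 700 pg of RNA with an integrity number above 8.5 was amplified and labeled with biotin. Per the submitters' processing notes, the authors made the values with RMA, which corrects background, normalizes arrays by quantiles and summarizes the probes of each probe set. The deposited values were read as log2 because they had the range of RMA output; the log base and the software version are not given in the sources used here. The largest values, from 17.61 to 18.23, exceeded 16, the log2 maximum of a 16-bit scanner, for a reason not given in the sources used here, so levels are meaningful only relative to each other.

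The table held 24351 probe sets, of which 2903 were controls (2809 HTA2, 63 ERCC and 31 AFFX). Of the 21448 gene probe sets, 17709 had 1 gene symbol and 3739 were unnamed here. XIST, TSIX and Y-linked genes (27 probe sets) were left out, and of probe sets for the same gene the one with the highest mean was kept, which dropped 19. This left 17663 genes, all matched by gene number to a RefSeq table of assembly GRCh38.p14, which was used for names and gene lengths only. The values were not normalized again. No detection call was available, and the level of background was unknown.

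Genes were tested with limma 3.58.1 in R 4.3.3, with statmod 1.5.0. A linear model with a mean for each of the 4 groups was fitted to all 12 arrays, which left 8 residual degrees of freedom, or 16.1 with limma's prior. The contrasts were shNNMT minus shCtrl in CAFs, NNMT minus control in WI-38, control CAFs minus control WI-38, and the interaction, that is the effect of more NNMT in CAFs minus that in WI-38. A gene passed, and is said to have risen, fallen or changed, at an adjusted p under 0.05 (Benjamini and Hochberg over all genes tested). The adjusted p-values of the report are those of limma, for genes from its moderated t test and for lists from camera. Standard errors and confidence intervals use the moderated variance, and values after ± are SDs over 3 arrays. A gene followed the NNMT level when it passed in both NNMT comparisons with opposite signs. Since 3 against 3 arrays can be split in only 10 ways, no permutation p can fall under 0.05, and the number of splits is given in the closing section.

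In all, 24 gene lists were fixed before the data were examined, with 600 genes of which 541 were measured. They were methionine and one-carbon metabolism, NAD and nicotinamide metabolism, histone and DNA methylation enzymes, extracellular matrix, TGF-beta response, contractile genes, fibroblast markers, proteases and their inhibitors, cytokines and chemokines, interferon response, cell cycle, p53 targets and senescence, amino acid starvation response, cholesterol and fatty acid synthesis, glycolysis and hypoxia, immediate early and heat shock genes, germline genes and HOX genes. Markers of adipocytes, of endothelial, epithelial and mesothelial cells, of leukocytes and of pericytes and smooth muscle completed them. The lists were written from general knowledge and some genes stand in more than 1. Camera compares the genes of a list with all other genes, with a preset correlation between genes of 0.01, and the p-values were adjusted over the 24 lists within each comparison. Counts adjusted over the list alone apply the correction to the genes of that list only.

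NNMT was named first. In each NNMT comparison the 10 largest increases and 10 largest decreases were named among passing genes whose arrays did not overlap between the groups, and 5 per direction between the control cells, among the genes that followed the NNMT level and in the interaction. Per list up to 4 passing members with the largest absolute change were named, or, with none passing, up to 2 with the smallest p. Genes without an official symbol, XIST and Y-linked genes were passed over. TGFB1, IL6, LIF, COL1A1 and ALDH1A1, named by these rules in one comparison, are also given in another.

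Alternatives chosen before the data were examined were a fit to only the 6 arrays compared, a trended and robust prior, quantile normalization, centring on array medians, removal of the dimmest 33.3% of genes, all 21371 gene probe sets, array weights, the replicate number as a block within each cell type, and leaving out each array. For the lists they were camera with an estimated correlation, fry, quantile normalization, the filter for dim genes, the block and leaving out each array. Estimating the correlation changed more than the correlation itself. In the interaction, adipocyte markers had an estimate of 0.00996, near the preset 0.01, yet camera's unadjusted p went from 0.0110 to 0.0345. A call lost in this setting is thus not always due to correlation between genes. Fry asks whether the genes of a list move on balance one way, without comparison with other genes. Leaving out both arrays that lay apart was added after the data were seen. The comparisons and tests were tested on simulated data before use. With 50 genes changed at each size among 17663, the knockdown design recovered 10%, 76%, 100% and 100% of changes of 0.5, 1, 2 and 3 log2 units, and the overexpression design 2%, 70%, 100% and 100%. Unchanged genes were called in 0.0458% and 0.0515% of cases. Far fewer genes were changed in the simulation than passed in the data (2953 and 3116), and the adjustment of p depends on that number. The shares of genes recovered and falsely called therefore do not carry over to the data. A shifted list of 26 genes was recovered in both designs and 0 other lists were called. The simulated noise was independent between genes, whereas the lists had estimated correlations of up to 0.155. Rates of false calls under such correlation were therefore not measured. Of the 63 ERCC control probe sets, 1, 0 and 2 passed in the knockdown, the overexpression and the comparison of control cells. Their median level was 5.20, near the lower quartile of the arrays, so these counts say little about false calls among brighter genes.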

Results

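Gene expression was measured on 12 Affymetrix arrays of human fibroblasts in which the level of nicotinamide N-methyltransferase (NNMT) had been lowered or raised. NNMT transfers the methyl group of S-adenosylmethionine to nicotinamide. Cancer-associated fibroblasts (CAFs), the fibroblasts of tumor stroma, carried a control hairpin construct (shCtrl) or a hairpin construct against NNMT (shNNMT). WI-38, an established line of normal human lung fibroblasts, carried a control construct or an NNMT expression construct. Each of the 4 groups held 3 arrays, which the labels call biological replicates. Nothing in the labels says that the replicates came from separate cultures or infections, so the p-values measure only the spread between these samples, which may be technical. All cells were grown for 21 days in medium with 10 µM methionine, the amino acid from which S-adenosylmethionine is made. Values were log2 RMA values, with array medians from 6.98 to 7.15 and lower quartiles from 4.87 to 5.01. The background level of the arrays was unknown, so a gene near or below the lower quartile was not separated from background. Where a group lay there, a fold change is a lower bound and its rank is not resolved. Control CAF replicate 3 and WI-38 NNMT replicate 1 lay farthest from their group mates, with mean correlations of 0.984 and 0.988 to them, against 0.989 to 0.995 for the other 10 arrays.

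NNMT itself moved in the direction of each construct. In CAFs its level fell from 10.74 ± 0.25 (SD, n = 3) to 8.39 ± 0.20 with shNNMT, which was 5.10-fold lower. The log2 fold change was -2.35 (95% confidence interval -2.87 to -1.84; limma adjusted p = 1.4e-05). In WI-38 its level rose from 8.0 ± 0.26 to 15.29 ± 0.52 with the NNMT construct, which was 156-fold higher. There the log2 fold change was 7.29 (95% confidence interval 6.77 to 7.80; limma adjusted p = 1.2e-11). The control groups of the cell types differed as well, since control CAFs held 6.68-fold more NNMT transcript than control WI-38 cells (log2 fold change 2.74, SE 0.24, adjusted p = 3.0e-07). In each of these comparisons the 3 arrays of one group all lay above the 3 of the other.

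**Figure D1:**
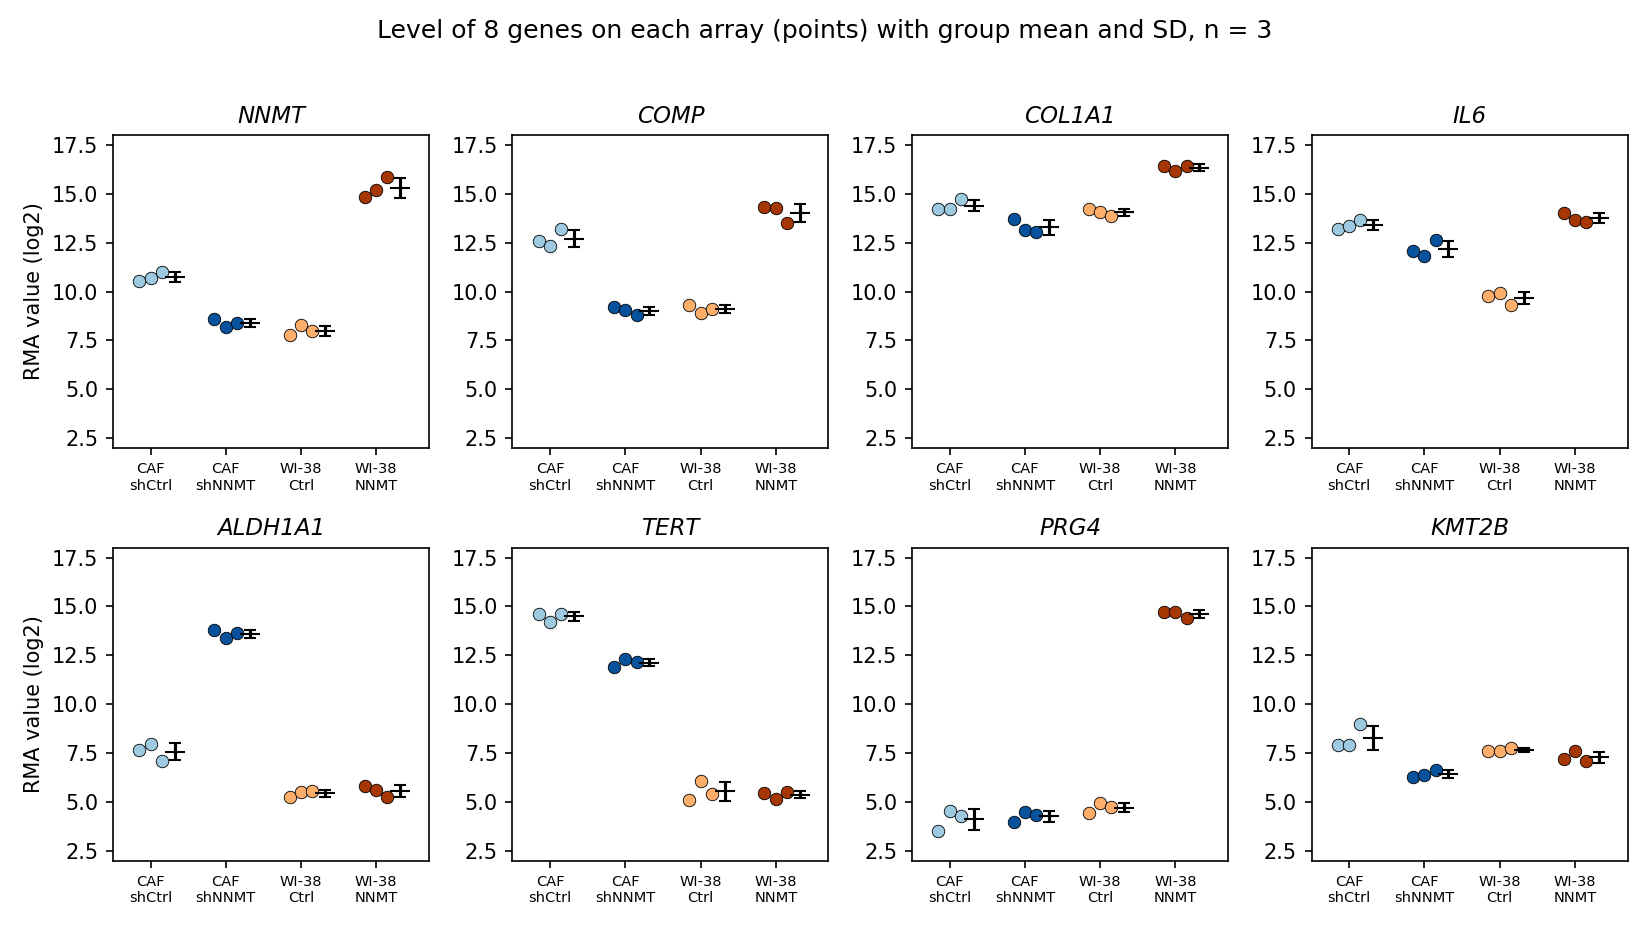
Each point is the log2 RMA value of a gene on an array, with the group mean and SD beside the 3 points of a group, for 8 genes in the 4 groups. NNMT lies at a mean of 10.74, 8.39, 8.0 and 15.29 in control CAFs, shNNMT CAFs, control WI-38 and NNMT WI-38, while COMP lies at 12.71, 9.02, 9.10 and 14.03.

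The knockdown comparison asked which genes changed in CAFs when NNMT was lowered. ALDH1A1, an aldehyde dehydrogenase that makes retinoic acid, rose 65.7-fold from 7.57 ± 0.44 to 13.61 ± 0.20 (SD, n = 3). TFPI2, a secreted inhibitor of serine proteases, rose 27.4-fold, NCAM1, the neural cell adhesion molecule, rose 19.6-fold, and CPE, a carboxypeptidase that processes peptide hormones, rose at least 14.1-fold. COMP, a secreted glycoprotein of cartilage and tendon matrix, was 12.9-fold lower, falling from 12.71 ± 0.44 to 9.02 ± 0.21. HTR1F, a serotonin receptor, was at least 9.82-fold lower, reaching the level of the lower quartile, and ABI3BP, a secreted matrix-binding protein, was 8.23-fold lower. TERT, the catalytic subunit of telomerase, was 5.16-fold lower, falling from 14.49 ± 0.24 to 12.12 ± 0.19. Whether the CAFs carried an introduced TERT gene is not said in the labels, so this fall is not assigned to the cells' own gene.

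Among the next largest increases after the knockdown were KRTAP1-5, a keratin-associated protein of hair, with a log2 fold change of 3.54, CST1, a cystatin that inhibits cysteine proteases, with 3.52, and ANGPT1, a ligand of the endothelial receptor TIE2, with 3.34. The aldo-keto reductases AKR1C3, AKR1C1 and AKR1C2 rose by 3.37, 3.18 and 3.11, but these genes are close in sequence and their probes can share signal, so the split between them is uncertain. Further decreases were those of COL15A1, a basement membrane collagen, with -2.54, E2F7, a repressor of cell cycle genes, with -2.38, and UNC5B, a netrin receptor, with -2.36. The near-identical GOLGA8B and GOLGA8A, with -2.38 and -2.31, are uncertain for the same reason as the aldo-keto reductases. The changes of CPE, HTR1F and AKR1C2 are lower bounds, since 1 group lay near or below the lower quartile. The standard errors of the log2 fold changes of the 20 genes with the largest changes lay between 0.16 and 0.35.

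Of the 17663 genes tested, 2953 (16.7%) passed limma's adjusted p in this comparison, 1425 higher and 1528 lower with shNNMT, and 639 and 485 of them changed at least 2-fold. The balance of both directions was not stable, since with each array centred on its median 1680 were higher and 1229 lower (763 and 391 at least 2-fold), and it also turned without control CAF replicate 2 (1277 and 1258) and without shNNMT replicate 2 (993 and 952) or 3 (889 and 866). In 87 of the 87 genes named in the knockdown comparison that passed, the 3 arrays of one group all lay above the 3 of the other, for the largest changes by the rule of their choice. The same held for 98.1% of all genes that passed, so it adds little to passing. The count of 2953 depended on single arrays, since it was 1755 without shNNMT replicate 3, 1945 without shNNMT replicate 2, and 4880 with array weights.

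Genes of histone and DNA methylation enzymes, which write or erase methyl marks with S-adenosylmethionine as the methyl donor for the writers, were lower after the knockdown. Of 35 measured, 0 rose, 14 fell and 21 did not pass, or 1 and 20 when adjusted over the list alone. The mean log2 fold change was -0.53, and the list passed camera, limma's test of a list against all other genes (adjusted p = 7.2e-06, or 0.0084 with an estimated correlation). The largest falls were those of KMT2B (-1.85, or 3.60-fold lower) and KMT2D (-1.29), which methylate lysine 4 of histone H3, EZH1 (-1.31), which methylates lysine 27, and KDM6B (-1.09), which demethylates lysine 27.

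Genes of the TGF-beta response were lower as well after the knockdown, with 1 rising, 11 falling and 14 not passing of 26 measured, or 2 and 13 when adjusted over the list alone. The mean was -0.58 and the camera adjusted p was 3.9e-05, with an adjusted p = 0.0877 with an estimated correlation. LRRC32, which tethers latent TGF-beta to the cell surface, fell by 2.25 on the log2 scale, LTBP2, a latent TGF-beta binding protein of microfibrils, fell by 2.03, the transcription factor BHLHE40 fell by 1.55, and the ligand gene TGFB1 fell by 1.10. Of 38 extracellular matrix genes, 5 rose, 13 fell and 20 did not pass, or 6 and 14 when adjusted over the list alone. COMP and COL15A1 led the falls, COL6A3, a chain of collagen VI, fell by 1.68 on the log2 scale, and FBLN1, an elastic fiber protein, rose by 1.74. The matrix list's mean was -0.35 (camera adjusted p = 0.0281, but adjusted p = 0.702 with an estimated correlation). Its call also ended without control CAF replicate 3 (0.0783), shNNMT replicate 2 (0.0686) or shNNMT replicate 3 (0.0857), without both arrays that lay apart (0.0844), and without the dimmest genes (0.0737).

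The other 21 lists did not pass camera in the knockdown comparison, although single members changed in most of them; counts over all genes are followed by those adjusted over the list alone. Among secreted factors, 4 of 30 cytokines and chemokines rose and 2 fell (5 and 2; adjusted p = 0.513): the chemokine CCL2 rose by 1.68, while the cytokines IL6 and LIF each fell by 1.23 on the log2 scale, or 2.34-fold and 2.35-fold, and IL24 lay at 1.12. Of 30 proteases and their inhibitors, 5 rose and 9 fell (5 and 10; adjusted p = 0.513), with ADAMTS5, an aggrecanase, at 1.81, ADAMTS2, a procollagen peptidase, at -1.39, the collagenase MMP1 at -1.06 and MMP10 at 0.98. Of 16 fibroblast markers, 3 rose and 3 fell (3 and 4; adjusted p = 0.866), with the proteoglycan DCN at 1.21, the receptor PDGFRB at -1.16, the collagen chain COL1A1 at -1.10 and TCF21 at 0.95. Of 22 contractile genes, 2 rose and 3 fell (4 and 4; adjusted p = 0.979), with smooth muscle actin, ACTA2, at 1.04, the non-muscle myosin MYH9 at -1.08, SMTN at -0.91 and CNN1 at 0.81. Of 35 interferon response genes, 3 rose and 2 fell (3 and 2; adjusted p = 0.866), with IFIT1 at 1.59, the transcription factor IRF1 at -1.38, PARP14 at -1.28 and IFIT3 at 0.83. Of 21 immediate early and heat shock genes, 1 rose and 3 fell (2 and 6; adjusted p = 0.513), with EGR1 at 1.55, FOSL1 at -1.25, KLF4 at -0.85 and IER3 at -0.74. The calls of IL24, MMP10, SMTN, CNN1, EGR1 and IER3 each ended under at least 1 alternative, and EGR1 lay at 0.90 without shNNMT replicate 3.

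None of the metabolic lists passed camera after the knockdown, while single members changed. Of 21 genes of methionine and one-carbon metabolism, 3 rose and 4 fell (3 and 4; adjusted p = 0.866), with methionine synthase, MTR, at -1.21, AMD1 at 1.18, MTHFD1L at -0.97 and MAT2B, a regulatory subunit of the enzyme that makes S-adenosylmethionine, at 0.91; the mean was -0.03 and the median lay just above 0. Of 22 genes of NAD and nicotinamide metabolism, 2 rose and 1 fell (2 and 1; adjusted p = 0.866), led by BST1, an ectoenzyme that cleaves NAD, at 1.86, with SIRT1 at -0.67 and SIRT5 at 0.57, and with a mean of 0.07 against a median of -0.07. Of 31 genes of the amino acid starvation response, 1 rose and 9 fell (2 and 9; adjusted p = 0.198), with the alanyl-tRNA synthetase AARS1 at -0.88, STC2 at -0.86, the cationic amino acid transporter SLC7A1 at -0.85 and VEGFA at -0.81, and after quantile normalization this list passed (adjusted p = 0.0249). Of 27 genes of glycolysis and hypoxia, 5 rose and 5 fell (7 and 7; adjusted p = 0.979), with the vasodilator peptide gene ADM at 1.22, the collagen prolyl hydroxylase P4HA2 at -1.22, PDK1 at 1.11 and PFKFB3 at -1.05. Of 22 genes of cholesterol and fatty acid synthesis, 3 rose and 2 fell (3 and 2; adjusted p = 0.979), with IDI1 at 1.63 and SC5D at 1.18, both of sterol synthesis, and ACACA at -1.11 and FASN at -1.07, both of fatty acid synthesis; the mean was 0.03, the median -0.23 and the direction of the test lower. The calls of AMD1, SIRT1, SIRT5, STC2, PDK1 and PFKFB3 each ended under at least 1 alternative, and AMD1 lay at 0.52 without control CAF replicate 3.

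Of 36 cell cycle genes in CAFs, 2 rose and 2 fell (2 and 1 adjusted over the list alone; adjusted p = 0.866), with the replication clamp PCNA at 1.01, CCNB1 at 0.89, MCM7 at -0.86 and PLK1 at -0.65. Of 19 p53 targets and senescence genes, 3 rose and 3 fell (5 and 6; adjusted p = 0.866), with SESN1 at 1.21, MDM2 at 0.90, XPC at -0.89 and CDKN1A, the p21 inhibitor, at -0.84; the mean lay just above 0, and the median of -0.05 and the test pointed lower. Markers of other cell types gave 1 rising and 0 falling of 11 adipocyte markers (1 and 0; adjusted p = 0.234; FABP4 at 2.27), 1 and 0 of 11 mesothelial markers (1 and 0; 0.866; MSLN at 0.73), 1 and 0 of 14 leukocyte markers (1 and 0; 0.866; CD68 at 0.73), 0 and 1 of 13 endothelial markers (0 and 1; 0.513; ESAM at -0.87) and 1 and 1 of 10 pericyte and smooth muscle markers (1 and 1; 0.866; CNN1 at 0.81, NOTCH3 at -0.73). The calls of PLK1, MDM2, MAGEA10, CD68, ESAM, CNN1 and NOTCH3 each ended under at least 1 alternative, FABP4 and ESAM lay below the lower quartile in 1 group, and MSLN and MAGEA10 lay below it in both, so their changes were not separated from background. PLK1 lost its call under most alternatives, among them quantile normalization, median centring, the trended prior and leaving out any single CAF array. Of 29 germline genes 1 rose and 0 fell (0 and 0; 0.866; MAGEA10 at 0.77). By limma, 0 of 19 epithelial markers and 0 of 23 HOX genes passed (0 adjusted over either list alone; camera adjusted p = 0.866 for both), and 2 in each list had an unadjusted p under 0.05. The epithelial markers with the smallest p, MUC16 at 0.70 and GRHL2 at -0.55, did not pass, nor did HOXB5 at 0.69 and HOXB2 at -0.86.

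The overexpression comparison asked which genes changed in normal fibroblasts when NNMT was raised. PRG4, which encodes the joint lubricant lubricin, rose from 4.71 ± 0.25, below the lower quartile, to 14.61 ± 0.19 (SD, n = 3), or at least 954-fold. COL11A1, a fibrillar collagen chain, rose 106-fold, CYP1B1, a cytochrome P450 that oxidizes estrogens and xenobiotics, rose 87.8-fold, and COMP rose 30.4-fold, from 9.10 ± 0.20 to 14.03 ± 0.46. IL6, an inflammatory cytokine, rose 17.1-fold and LIF, a related cytokine, 11.5-fold. MAMDC2, a secreted protein with MAM domains, was 93.5-fold lower, falling from 14.29 ± 0.37 to 7.74 ± 0.34. BMP4, a ligand of the BMP family, was 21.2-fold lower and MYC, a growth-promoting transcription factor, 8.31-fold lower.

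The largest increases with NNMT in WI-38 also held LSAMP, a neuronal adhesion molecule, with a log2 fold change of 6.24, RSPO3, a potentiator of WNT signaling, with 6.10, CRABP2, which carries retinoic acid, with 5.86, AFF2 with 5.18 and JAM2, a junctional adhesion molecule, with 4.78. The largest decreases also held LYPD1 with -5.00, ANKRD1, a target of the YAP transcriptional coactivator, with -4.95, ADAMTS5 with -4.27, EPB41L3, a membrane skeleton protein, with -4.07, ULBP1, a ligand of the NKG2D receptor, with -3.93 and A2M, a broad protease inhibitor, with -3.71. FRMPD4 with -3.67 and the phosphodiesterase PDE10A with -3.60 followed. The changes of PRG4, LSAMP, RSPO3, EPB41L3 and PDE10A are lower bounds, since 1 group lay below the lower quartile. All but BMP4, whose SE was 0.58, had standard errors between 0.20 and 0.37.

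Of the 17663 genes tested, 3116 (17.6%) passed limma's adjusted p with NNMT overexpression, 1405 higher and 1711 lower, and 722 and 814 of them changed at least 2-fold (755 and 716 after quantile normalization, 723 and 675 without WI-38 NNMT replicate 1, 736 and 696 without both arrays that lay apart). In 87 of the 87 genes named in the overexpression comparison that passed, the 3 arrays of one group all lay above the 3 of the other, for the largest changes by the rule of their choice. The same held for 98.3% of all genes that passed there, so it adds little to passing.

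Extracellular matrix genes rose as a list with NNMT in WI-38. Of 38 measured, 22 rose, 4 fell and 12 did not pass, and the counts were again 22 and 4 when adjusted over the list alone. The mean log2 fold change was 1.01 (camera adjusted p = 4.0e-10, or 0.037 with an estimated correlation). Besides COL11A1 and COMP, the elastic fiber protein FBLN2 rose by 2.71 and COL1A1, a chain of collagen I, rose 4.90-fold, while COL10A1, a collagen of hypertrophic cartilage, fell by 2.98 on the log2 scale. Cytokines and chemokines rose too, 9 of 30 rising and 0 falling (9 and 0 adjusted over the list alone). Their mean was 0.73, with a median of 0.17 (camera adjusted p = 0.00016, or 0.0277 with an estimated correlation). IL6 rose by 4.10 on the log2 scale, LIF by 3.53, the neutrophil chemokine CXCL8 by 3.11 and IL1B by at least 2.94, from below the lower quartile. Cell cycle genes were higher, with 13 of 36 rising and 2 falling (14 and 3 adjusted over the list alone), a mean of 0.51 and a camera adjusted p of 0.00012 (0.015 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, rose 6.76-fold, the replication licensing factor CDC6 rose by 2.10, the cyclin CCNA2 by 1.45 and RRM2, a subunit of ribonucleotide reductase, by 1.5, a call that ended under at least 1 alternative.

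Genes of the amino acid starvation response, targets of the transcription factor ATF4 among them, were lower with NNMT in WI-38. Of 31 measured, 2 rose, 16 fell and 13 did not pass, or 3 and 19 when adjusted over the list alone. The mean was -0.59 (camera adjusted p = 7.0e-06, or 0.015 with an estimated correlation). CHAC1, which degrades glutathione, was 5.39-fold lower, asparagine synthetase, ASNS, fell by 1.58 on the log2 scale, PHGDH, which opens serine synthesis, fell by 1.39, and the neutral amino acid transporter SLC1A4 fell by 1.38. Contractile genes were lower, with 1 of 22 rising and 10 falling (2 and 12 adjusted over the list alone). Their mean was -0.55 (camera adjusted p = 0.00012, but adjusted p = 0.0703 with an estimated correlation). Calponins CNN2 and CNN1 fell by 1.88 and 1.19, LMOD1, which nucleates actin filaments, fell by 1.65, and the actin cross-linker PALLD fell by 1.23. P53 targets and senescence genes gave 2 rising and 8 falling of 19 (3 and 10 adjusted over the list alone). Their mean was -0.43 (camera adjusted p = 0.00333, but adjusted p = 0.239 with an estimated correlation). The members went both ways, since the p53-induced AEN and GDF15 fell by 1.54 and 1.44, while CDKN2A and CDKN2B, which encode inhibitors of cyclin-dependent kinases, rose by 1.58 and 1.48. The median of this p53 list on WI-38 NNMT replicate 1 lay at -0.35 relative to the other two arrays of its group.

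Fibroblast markers, interferon response genes and mesothelial markers were higher with NNMT in WI-38, but the calls of all 3 lists ended with an estimated correlation. Of 16 fibroblast markers, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a mean of 0.61 (camera adjusted p = 0.00161, adjusted p = 0.134 with an estimated correlation). S100A4 rose by 2.37, COL1A1 by 2.29 and the proteoglycans LUM and DCN by 2.18 and 0.88. Of 35 interferon response genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with a mean of 0.39 (camera adjusted p = 0.00189, adjusted p = 0.0703 with an estimated correlation). SAMD9, an antiviral factor, rose by 3.39, USP18, which removes ISG15, by 2.10 and IRF1 by 1.22, whereas XAF1 fell by 1.56, a call that ended under at least 1 alternative. Of 11 mesothelial markers, 3 rose and 0 fell (3 and 0 adjusted over the list alone), with a mean of 1.54 and a median of 0.16 (camera adjusted p = 0.00224, adjusted p = 0.0582 with an estimated correlation). The mesothelial genes that rose were PRG4, the zinc finger gene BNC1 by 3.88 and calretinin, CALB2, by 2.93. For the TGF-beta response, 9 of 26 rose and 3 fell (10 and 3 adjusted over the list alone), with a mean of 0.33 (camera adjusted p = 0.0243, adjusted p = 0.2245 with an estimated correlation). COL1A1 and ID1, a target of BMP signaling, rose by 2.29 and 2.01, whereas INHBA, a subunit of activin, and CCN2, connective tissue growth factor, fell by 2.16 and 1.45. The TGF-beta call also ended without WI-38 NNMT replicate 1 (0.0638) and without both arrays that lay apart (0.0585).

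The other 14 lists did not pass camera in the overexpression comparison; counts are again followed by those adjusted over the list alone. Of 30 proteases and their inhibitors, 8 rose and 6 fell (9 and 6; adjusted p = 0.854), with a mean of -0.24 against a median of 0.02. The matrix metalloproteinases MMP1, MMP19 and MMP3 were among those that fell, by 3.02, 2.83 and 2.72 on the log2 scale. Of 21 immediate early and heat shock genes, 5 rose and 6 fell (7 and 7; adjusted p = 0.854), with KLF4 at 2.70, EGR1 at 2.12, MYC at -3.05 and DUSP1 at -2.16. Of 21 genes of methionine and one-carbon metabolism, 2 rose and 4 fell (2 and 4; adjusted p = 0.565). Cystathionine beta-synthase, CBS, lay at -1.49 and the next enzyme of that pathway, CTH, at 0.96, while AMD1, which decarboxylates S-adenosylmethionine for polyamine synthesis, lay at -2.04 and AHCYL1 at 1.19. Of 22 genes of NAD and nicotinamide metabolism, 2 rose and 4 fell (4 and 4; adjusted p = 0.642), with NMNAT2, which makes NAD, at 1.73, the deacetylase SIRT2 at -1.29, BST1 at -1.10 and QPRT at 0.79. Of 35 histone and DNA methylation enzymes, 2 rose and 2 fell (1 and 2; adjusted p = 0.761), with the demethylase KDM5A at -1.75, SUV39H1 at -1.10, DNMT3A at 0.94 and KDM5B at 0.65. The call of QPRT ended under at least 1 alternative. That of KDM5B ended under most, among them median centring and leaving out any single WI-38 array except NNMT replicate 2. Of 27 genes of glycolysis and hypoxia, 3 rose and 5 fell (4 and 5; adjusted p = 0.542), with the glucose transporter SLC2A3 at -2.83, ADM at -2.12, carbonic anhydrase CA12 at 2.09 and P4HA1 at 1.43.

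Of 22 genes of cholesterol and fatty acid synthesis in WI-38, 0 rose and 3 fell (0 and 3 adjusted over the list alone; adjusted p = 0.298), namely ELOVL6 at -1.32, FADS2 at -0.72 and FDPS at -0.72, each of which lost its call under at least 1 alternative. Markers of other cell types gave 1 rising and 0 falling of 11 adipocyte markers (1 and 0; 0.144; PPARG at 1.17), 1 and 1 of 13 endothelial markers (1 and 1; 0.642; ESAM at -0.95, VWF at 0.60), 0 and 2 of 19 epithelial markers (0 and 2; 0.768; KRT18 at -1.87, KRT8 at -0.91) and 0 and 2 of 10 pericyte and smooth muscle markers (1 and 2; 0.854; CNN1 at -1.19, SYNPO2 at -0.85). The calls of VWF, KRT8 and SYNPO2 each ended under at least 1 alternative. The epithelial mean lay just below 0 with a median of 0.21 and a test pointing higher, and the pericyte mean was -0.05 with a median of 0.09. By limma, 0 genes passed among 29 germline genes (camera adjusted p = 0.854), 23 HOX genes (0.212) and 14 leukocyte markers (0.141), where 4, 3 and 5 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. Their members with the smallest p did not pass: SYCP2 at -0.60 and SOHLH2 at -0.58, HOXA2 at 0.68 and HOXB2 at 0.93, and PTPRC at 0.60 and CSF1R at 0.59.

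**Figure D2:**
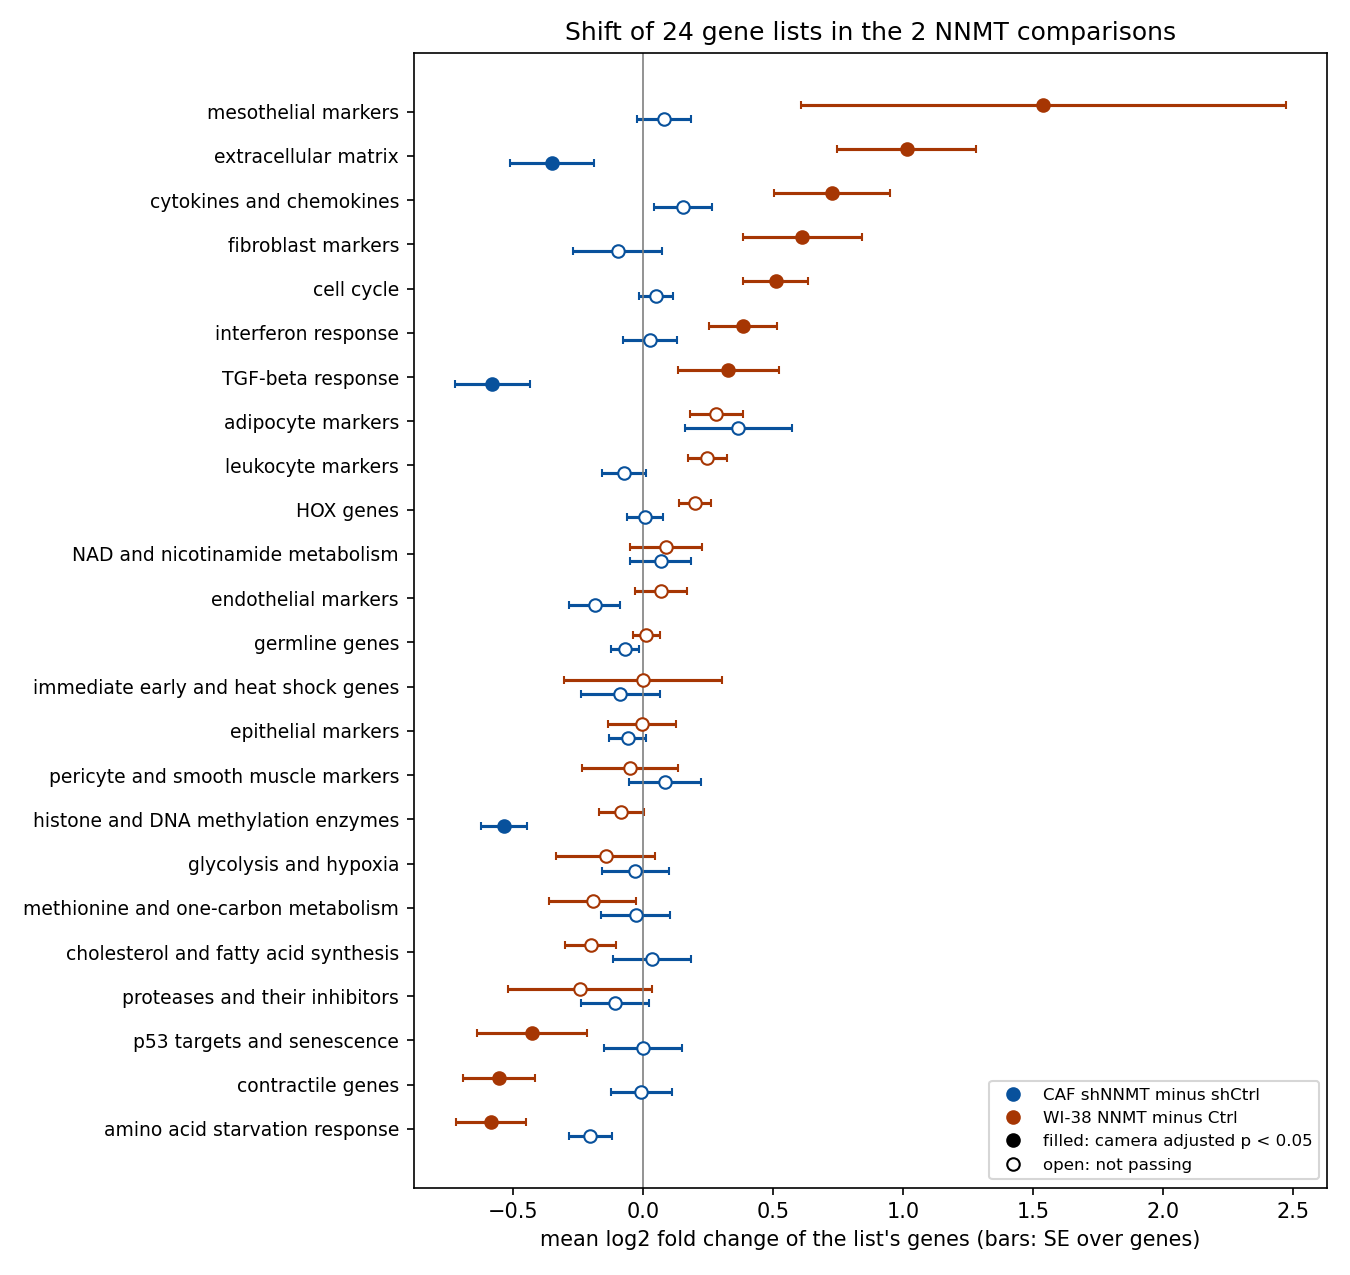
Each point is the mean log2 fold change of the genes of a list, with a bar for the standard error over genes, for 24 lists in the knockdown in CAFs (blue) and the overexpression in WI-38 (brown); filled points passed camera's adjusted p. Extracellular matrix genes lie at -0.35 after the knockdown and at 1.01 with overexpression, and histone and DNA methylation enzymes at -0.53 after the knockdown.

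Since the arms manipulate the same gene in opposite directions, genes that moved with the NNMT level in both cell types were those with opposite signs in the 2 comparisons. Of the genes lower after knockdown and higher with overexpression, COMP changed by -3.69 in CAFs and 4.93 in WI-38, CYP1B1 by -1.68 and 6.46, ABI3BP by -3.04 and 4.43, and PAPPA2, a protease of IGF-binding proteins, by -1.29 and 4.38. IL6, LIF, COL1A1 and TGFB1 went the same way, with 4.10, 3.53, 2.29 and 1.42 in WI-38 against -1.23, -1.23, -1.10 and -1.10 in CAFs. Of the genes higher after knockdown and lower with overexpression, BMP4 changed by 3.06 and -4.41, ANKRD1 by 1.62 and -4.95, ADAMTS5 by 1.81 and -4.27, and MYOCD, a coactivator of smooth muscle genes, by 2.58 and -3.37. MAMDC2 changed by 1.08 and -6.55, though its call in CAFs ended under at least 1 alternative. BMP4 lay at -2.79 on control CAF replicate 3 relative to the other control CAF arrays, which enlarged its change of 3.06 in CAFs.

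In all, 423 genes passed in both comparisons with opposite signs, 193 of them higher and 230 lower with more NNMT. Independent lists of the same sizes would share 121.5 and 138.0, so the overlap was 1.63 times the 259.6 of both. With each array centred on its median the split was 145 and 298, after quantile normalization 218 and 206, without control WI-38 replicate 2 153 and 149, and without both arrays that lay apart 265 and 264. Genes with the same sign in both comparisons numbered 462, which was 1.77 times the 261.4 of independent lists, with 221 higher in both (113.4) and 241 lower in both (148.0). CPE, with 3.81 and 3.48, and KRTAP1-5, with 3.54 and 4.05, rose in both, the 3.81 and the 4.05 being lower bounds. DSP, which encodes desmoplakin of cell junctions, fell in both, with -1.77 and -3.04. Over the 17663 genes the log2 fold changes of the 2 comparisons had a Pearson correlation of -0.016 and a Spearman correlation of -0.019, across genes that are not independent replicates. The count of 423 was 261 without shNNMT replicate 3 and 657 with array weights.

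**Figure D3:**
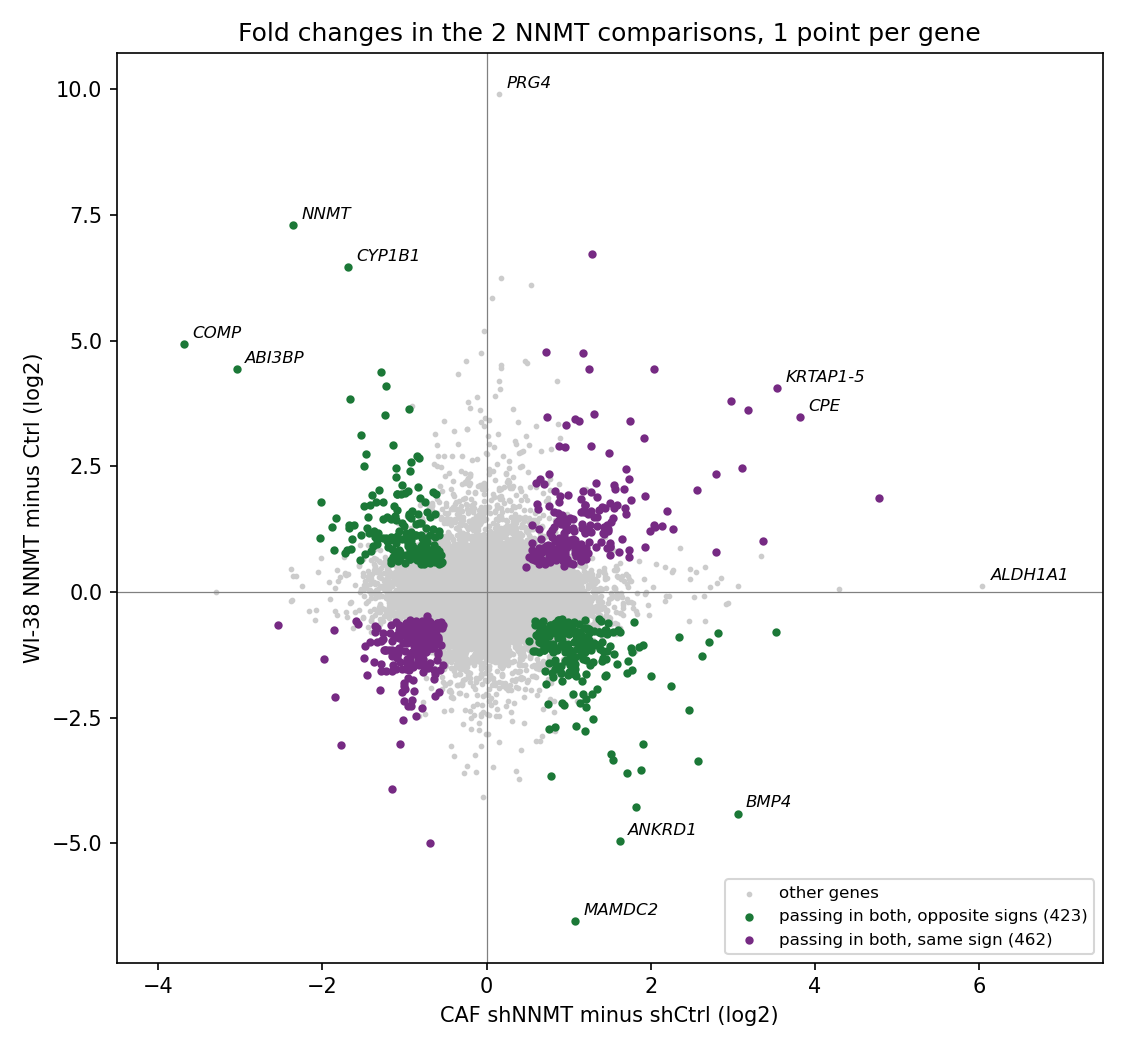
Each point is a gene, with its log2 fold change in CAFs (shNNMT minus shCtrl) on the horizontal axis and in WI-38 (NNMT minus control) on the vertical axis; green points passed in both with opposite signs (423) and purple points with the same sign (462). COMP lies at -3.69 and 4.93, BMP4 at 3.06 and -4.41, and CPE at 3.81 and 3.48.

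Whether the response to NNMT differed between the arms was tested with an interaction contrast, the effect of more NNMT in CAFs minus that in WI-38. It passed for 3176 of the 17663 genes (18%), with the CAF effect above the WI-38 effect in 1756 and below it in 1420. The cell type, the kind of construct and the size of the NNMT change (log2 -2.35 in CAFs, 7.29 in WI-38) differed together between the arms. A difference can therefore not be assigned to the cell type. LYPD1 had a positive difference of 5.69 (SE 0.28, adjusted p = 1.7e-09) and PRG4 a negative difference of -10.04 (SE 0.35, adjusted p = 5.8e-11), a size that is not resolved because PRG4 lay near or below the lower quartile in every group but NNMT WI-38. For PRG4 the change in CAFs was 0.15 and did not pass. COL11A1 rose in both comparisons, by 1.28 after the knockdown and by 6.72 with overexpression, so that its interaction was -8.0. The interaction of ALDH1A1 was -6.16, with a change of 0.12 in WI-38 that did not pass, and that of NNMT was -4.94.

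Control CAFs and control WI-38 cells were compared to describe the backgrounds of the 2 arms; cell type, tissue and control construct differed together. TERT was far higher in CAFs, 14.49 ± 0.24 in control CAFs against 5.54 ± 0.50 in control WI-38 (SD, n = 3), which was 495-fold, though an introduced TERT gene in the CAFs is neither stated nor denied in the labels. CCL2, a monocyte chemokine, was at least 414-fold higher in CAFs (12.72 ± 0.32 against 4.03 ± 0.45, below the lower quartile), and SULF1, a heparan sulfate sulfatase, PTX3, a secreted pentraxin, and HTR2B, a serotonin receptor, were higher by 7.62, 7.57 and 7.57 on the log2 scale. CDH6, a cadherin, was 1049-fold lower in CAFs (5.63 ± 0.33 against 15.67 ± 0.11), TGFBI, a matrix protein induced by TGF-beta, 1009-fold lower and MMP1 351-fold lower. SLITRK6 and LRRC17 lay at -8.21 and -7.75, SLITRK6 from below the lower quartile in CAFs. Of 17663 genes, 4161 (23.6%) passed limma's adjusted p, 1901 higher and 2260 lower in CAFs, and 894 and 1143 differed at least 2-fold. After quantile normalization 2113 were higher and 1984 lower. The arrays of both groups did not overlap in 84 of the 85 named genes, ACTA2 being the exception, though the largest differences were chosen that way. Nor did they in 97.6% of all genes that passed, so this adds little to passing.

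Interferon response genes were higher in control CAFs, with 16 of 35 higher and 0 lower (19 and 2 adjusted over the list alone), a mean of 0.95 and a camera adjusted p of 3.8e-08 (0.0228 with an estimated correlation). XAF1, IFIT1, IFIT2 and the RNA sensor IFIH1 were higher by 3.72, 3.15, 2.63 and 2.52. XAF1 lay at -2.24 on control CAF replicate 3 relative to the other two control CAF arrays, which lowered its difference, and IFIH1 lay near the lower quartile in WI-38. Proteases and their inhibitors were lower, with 2 of 30 higher and 13 lower (3 and 14 adjusted over the list alone), a mean of -1.04 and a camera adjusted p of 2.7e-05 (0.031 with an estimated correlation). After MMP1, ADAM19 lay at -3.50, and the urokinase PLAU and its receptor PLAUR at -3.07 and -2.90. Of 26 TGF-beta response genes, 2 were higher and 14 lower (2 and 14 adjusted over the list alone), with a mean of -0.92 (camera adjusted p = 0.000265, adjusted p = 0.0855 with an estimated correlation). PMEPA1 and LTBP1 lay at -3.41 and -2.30, and LRRC32 at 3.39. Of 30 cytokines and chemokines, 8 were higher and 1 lower (8 and 1 adjusted over the list alone), with a mean of 0.68 (camera adjusted p = 0.00941, adjusted p = 0.0855 with an estimated correlation). IL6 lay at 3.74, CSF1 at 1.43 and IL11 at -1.49, and the call ended without both arrays that lay apart (0.0536).

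Of 22 contractile genes, 1 was higher and 6 lower in control CAFs (1 and 7 adjusted over the list alone), with a mean of -0.53 (camera adjusted p = 0.0269, adjusted p = 0.337 with an estimated correlation). The enteric actin ACTG2 lay at -5.02, CNN1 at -1.47, the adhesion protein VCL at -0.90 and ACTA2 at -0.78, the last a call that ended under at least 1 alternative. Of 19 p53 targets and senescence genes, 1 was higher and 9 lower (1 and 10 adjusted over the list alone), with a mean of -0.38 (camera adjusted p = 0.042, adjusted p = 0.459 with an estimated correlation). SPATA18 lay at -1.94, CDKN2A at 1.93, ZMAT3 at -1.25 and TP53INP1 at -1.20, and on control CAF replicate 3 the list's median lay at -0.43 relative to the other two control CAF arrays. The contractile call ended with quantile normalization (0.0882), without the dimmest genes (0.113), without control CAF replicate 1 (0.0710) and without control WI-38 replicate 2 (0.0519). The p53 call ended with quantile normalization (0.132), without the dimmest genes (0.121), without control CAF replicate 3 (0.141), without control WI-38 replicate 2 (0.0912) and without both arrays that lay apart (0.149).

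The other 18 lists did not pass camera between the control cells; counts higher and lower in CAFs are followed by those adjusted over the list alone. Extracellular matrix genes split evenly, with 13 of 38 higher and 13 lower (14 and 13; adjusted p = 0.437). MFAP5, a microfibril protein, and THBS2, a thrombospondin, lay at 5.83 and 5.18, against COL10A1 at -5.54, from below the lower quartile in CAFs, and CTHRC1 at -5.31. Of 16 fibroblast markers, 6 were higher and 6 lower (6 and 6; adjusted p = 0.993), with LUM at 3.57, the transcription factor TCF21 at -5.47, PDPN at -2.0 and DCN at -1.36. Of 23 HOX genes, which mark position along the body axis, 1 was higher and 5 lower (1 and 5; adjusted p = 0.386), with a mean of -0.77 and a median of 0.11. HOXB6, HOXB2, HOXB5 and HOXB7 lay at -4.91 (below the lower quartile in CAFs), -4.81, -4.72 and -4.61, and without the dimmest genes the HOX list passed (0.00817). Of 27 genes of glycolysis and hypoxia, 3 were higher and 8 lower (3 and 8; adjusted p = 0.181), with CA12 at 4.10, PFKFB3 at -3.14, the glucose transporter SLC2A1 at -3.07 and NDRG1 at -2.05. Of 31 genes of the amino acid starvation response, 8 were higher and 1 lower (8 and 1; adjusted p = 0.301), with DDIT4 at 2.26, VLDLR at -1.54, PSPH at 1.11 and SLC7A5 at 1.01.

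In the same comparison, 4 of 36 cell cycle genes were higher and 5 lower (4 and 5 adjusted over the list alone; adjusted p = 0.993; MCM6 at 1.66, MCM5 at -1.54, TYMS at -1.17, MCM7 at -1.15). Of 22 genes of cholesterol and fatty acid synthesis 3 were higher and 7 lower (3 and 7; 0.360; ELOVL6 at -1.67, ACLY at -1.33, IDI1 at -1.12, STARD4 at 0.96). For histone and DNA methylation enzymes the counts were 2 and 5 of 35 (2 and 5; 0.491; KMT2D at -1.38, KMT2A at -1.24, TET2 at -0.99, KMT2C at -0.72), for immediate early and heat shock genes 3 and 5 of 21 (5 and 5; 0.993; DUSP1 at -1.59, KLF4 at 1.24, FOSL1 at -1.07, HSPH1 at -0.89), for methionine and one-carbon metabolism 3 and 3 of 21 (3 and 3; 0.993; AHCY at 1.20, TYMS at -1.17, MAT2B at 1.16, SMS at -0.95), and for NAD and nicotinamide metabolism 2 and 1 of 22 (2 and 1; 0.993; BST1 at -3.08, AOX1 at 1.01, NAMPT at 0.91). Germline genes gave 1 and 1 of 29 (0 and 1; 0.993; SOHLH2 at -1.0, MAGEC2 at 0.60). Endothelial markers gave 0 and 3 of 13 (0 and 3; 0.207; TEK at -4.54, ESAM at -1.03, EMCN at -0.58), pericyte and smooth muscle markers 1 and 3 of 10 (1 and 3; 0.240; ACTG2 at -5.02, CNN1 at -1.47, KCNJ8 at 1.03, CSPG4 at -0.84), epithelial markers 0 and 1 of 19 (0 and 1; 0.771; KRT8 at -2.07), leukocyte markers 0 and 1 of 14 (0 and 1; 0.993; CD68 at -1.96), mesothelial markers 0 and 1 of 11 (0 and 1; 0.437; BNC1 at -0.65) and adipocyte markers 0 and 1 of 11 (0 and 1; 0.613; PPARG at -1.07). The calls of IDI1, TET2, KMT2C, AHCY, NAMPT, MAGEC2, EMCN and BNC1 each ended under at least 1 alternative, and DUSP1 lay at -0.94 without control CAF replicate 3. Mean and median differed in sign for epithelial markers (-0.15 and 0.06), leukocyte markers (-0.06 and 0.03), methionine and one-carbon metabolism (-0.03 and 0.03), NAD and nicotinamide metabolism (-0.10 and 0.01), and germline genes (-0.03 and 0.02, with the test pointing higher). The immediate early list had a mean just above 0 and a median of -0.03, with the test pointing lower.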

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

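The tests of the 3 patterns weighed here were chosen after the patterns were seen, with their bounds written before each test was run. The list tests of the interaction, the overexpression part of the test without both arrays that lay apart, and the bound on foreign RNA from the genes that fell were chosen only after the results were seen. The statistic of the tests on residuals was rewritten after a first version had been run, to match camera's own. The verdicts on a change in the share of other cells and on the splits of both cell types were revised after their results were seen.

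A difference between the arms in the response to NNMT, tested with limma's interaction contrast, marked 3176 genes. Cell type, kind of construct and size of the NNMT change differed together, so the difference cannot be assigned to the cell type. The effect of more NNMT in CAFs exceeded that in WI-38 most for LYPD1 (5.69), MAMDC2 (5.47), ULBP1 (5.08), DSP (4.81) and EPB41L3 (4.11). It lay farthest below that in WI-38 for PRG4 (-10.04), COL11A1 (-8.0), KRTAP1-5 (-7.59), CPE (-7.30) and AKR1C1 (-6.81; paralogs share signal). For EPB41L3, PRG4, KRTAP1-5 and CPE a group lay near or below the lower quartile of the arrays, so size and rank are not resolved. CPE, KRTAP1-5 and AKR1C1 rose in both comparisons, although NNMT was lowered in one and raised in the other.

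The same difference marked 10 lists, given as the mean of the CAF effect minus the WI-38 effect with camera's adjusted p and then that with an estimated correlation. Amino acid starvation response was at 0.79 (6.4e-06, 0.0141), cytokines and chemokines at -0.88 (0.000108, 0.0141), cell cycle at -0.56 (0.000613, 0.0141), histone and DNA methylation enzymes at 0.62 (0.000613, 0.0141) and mesothelial markers at -1.62 (0.00121, 0.0386). The median of the 11 mesothelial markers was only -0.29, and PRG4, whose size is not resolved, lay at -10.04 among them. Contractile genes at 0.56 (0.00304, 0.165), extracellular matrix at -0.66 (0.00304, 0.274), interferon response at -0.41 (0.0110, 0.138), adipocyte markers at -0.65 (0.0293, 0.138) and p53 targets and senescence at 0.43 (0.0360, 0.392) lost the call with an estimated correlation.

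Outside the genes tested, changes were also seen among the probe sets unnamed here, after those on the Y chromosome were left out. Of the 3689 left, 451 (12.2%) changed with the knockdown, 133 higher and 318 lower, and 355 (9.62%) with the overexpression, 140 higher and 215 lower. Both shares lay below the 16.7% and 17.6% of the genes tested, so the unnamed probe sets did not stand out.

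Control CAF replicate 3 and WI-38 NNMT replicate 1 lay apart from their group mates. A technical deviation shared by both remained open, since their deviations correlated at r = 0.450 over genes. This was the largest of 54 pairs of arrays from different groups. The next, control CAF replicate 2 with WI-38 NNMT replicate 1 (-0.383), shares an array with it. Deviations within a group also depend on each other, so the rank among the pairs adds little. RNA of WI-38 cells in the CAF array was excluded, since genes far higher in WI-38 had a median deviation of -0.165. For CAF RNA in the WI-38 array the median of 0.183 met its bound only narrowly. Control WI-38 replicate 2, which did not lie apart, had a median of 0.244, so a small share of CAF RNA was not excluded. Excluded was CAF RNA as the source of the 424 genes that fell by at least 1 log2 unit there. These falls would need 50% foreign RNA and a median rise of 6.0. No group of the design holds both arrays, so a biological explanation remained untested.

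Histone and DNA methylation enzymes were lower after the knockdown. A trend of the fold change with gene length and level was excluded, since limma's camera, over the 35 genes of the list against the others, gave 8.8e-07 (unadjusted) on the residuals. The length used was that of the gene (median 68118 bases in the list, 25914 over all genes). A trend with transcript length was not tested. An effect of control CAF replicate 3 alone was excluded, with an adjusted p of 5.1e-06 without that array. Lower NNMT itself remained open, and because the labels do not say how many hairpins were used, it was not separated from an effect of the construct.

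Extracellular matrix genes were called lower after the knockdown and higher with overexpression, but the knockdown call was lost with an estimated correlation (adjusted p = 0.702, against 0.037 in the overexpression). The arrays that lay apart remained open as an explanation of the knockdown part, since its adjusted p was 0.0844 without both, although the mean moved only from -0.35 to -0.32. The loss was not particular to them, since the call also ended without shNNMT replicate 2 (camera adjusted p = 0.0686) or 3 (0.0857), which did not lie apart. For the overexpression part the arrays that lay apart were excluded (adjusted p = 2.8e-09 without both). A trend with gene length and level was excluded (camera on residuals gave 0.00290, unadjusted, the higher of both comparisons), while transcript length was again not tested. A change in the share of other cells remained open: 0 of the 6 other cell type lists passed camera in the direction needed, which had been set beforehand as the bound, but a list that misses the threshold excludes nothing, and the lists went both ways, adipocyte markers having a mean of 0.37 after the knockdown (median 0.17, with FABP4 the only gene that passed) but of 0.28 with overexpression, against the direction needed, as mesothelial markers did (1.54). The NNMT level as the cause remained open.

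Chance was examined by regrouping arrays. For the knockdown, 1 of 10 splits gave as many genes (2953, highest other 0), 1 as many genes changed at least 2-fold (1124, highest other 0) and 2 as many lists (3, highest other 3). For the overexpression the numbers were 1 (3116 genes, highest other 0), 1 (1536 genes, 0) and 1 (10 lists, highest other 6), and for the control cells 1 (4161 genes, 0) and 1 (6 lists, highest other 4). These 10 splits are too few for a share under 0.05. In each of the comparisons most of the other splits, where 0 genes passed, still called lists by camera with the preset correlation. Such splits keep part of the real contrast, so this gives no rate of false calls, but the list calls are less certain than their p-values. Over 100 of the 200 splits of both cell types at once, 1 gave as many genes following the NNMT level (423, highest other 0) and 1 as many interaction calls (3176, highest other 1433). These counts decide nothing about chance overlap, because no other split of either cell type alone called a gene, which fixes the first count at 0. The split that reverses the WI-38 labels was not drawn and would give the 462 genes of the same sign.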

How the results depend on the processing

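The setting without both arrays that lay apart was chosen only after the results were seen. The counts of genes stayed within 1.5 times under all settings except those named here, but the balance of higher and lower calls turned under some scalings and without some arrays. Median centring turned the knockdown from 1425 higher and 1528 lower to 1680 and 1229. Quantile normalization turned the control cells from 1901 and 2260 to 2113 and 1984, the overexpression at 2-fold from 722 and 814 to 755 and 716, and the genes following NNMT from 193 and 230 to 218 and 206; the cause was not tested. Leaving out control CAF replicate 2 or shNNMT replicate 2 or 3 turned the knockdown, control WI-38 replicate 2 the genes following NNMT, WI-38 NNMT replicate 1 the overexpression at 2-fold, and both arrays that lay apart the last 2 of these. With array weights 4880 genes changed with the knockdown and 657 followed the NNMT level; the cause was not tested. Leaving out 1 array at a time gave 1755 (without shNNMT replicate 3; 1945 without shNNMT replicate 2) to 3004 genes for the knockdown and 261 to 498 that followed the NNMT level, with fewer arrays in each fit. With an estimated correlation 1, 4 and 2 lists passed in the knockdown, the overexpression and the control cells, against 3, 10 and 6 with the preset one; fry, which asks a different question, called 7, 15 and 14. With the replicate number as a replicate block the counts of genes were 2596, 2855 and 3880, with 2878 for the interaction and 359 that followed the NNMT level. Within a cell type, the deviations of same-numbered arrays from their group means correlated at -0.187 to 0.149. Those of arrays with different numbers correlated at -0.245 to 0.383, so the number does not pair the arrays. The block ended 1 list call, p53 targets and senescence between the control cells (0.0523). Without both arrays that lay apart 3640, 3396 and 4385 genes passed, and 2, 9 and 4 lists. Of the genes that passed and were named, here including for the NNMT comparisons those named as following the NNMT level, 74 of 93 kept their call in the knockdown, 80 of 90 in the overexpression and 76 of 85 between the control cells under the 14 settings run for single genes, and 10 of 10 in the interaction under 19, and none reversed. The fit to all gene probe sets was not among these settings, and the filter for dim genes held only 90, 85, 83 and 9 of them. The level of background was unknown, so how far it limits the dim genes was not measured.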

Other observations

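Beside the 423 genes that moved in opposite directions when NNMT was lowered in CAFs and raised in WI-38, 462 moved the same way. The count of 462 was not taken under any alternative, so which group is larger was not settled. The aldo-keto reductase AKR1C1 rose by 3.18 and 3.62 and CPE by 3.81 and 3.48, with SEs of 0.19 and 0.23, but the paralogs of AKR1C1 share signal.

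TERT lay at 14.49 ± 0.24 in control CAFs, 12.12 ± 0.19 in shNNMT CAFs and 5.54 ± 0.50 in control WI-38 (SD, n = 3). The labels do not say whether the CAFs carried an introduced TERT gene.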
